A study of Mus musculus with 6 samples.

How the data were processed

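Total RNA of sorted prostate macrophages was amplified from 100 ng, labelled with Cy3 and hybridised to Agilent mouse arrays with 1 colour, per the labels' protocols. The 6 arrays were grouped by their treatment label into untreated and aCXCR2, 3 in each, and replicate numbers were taken from the sample titles. Nothing in the labels gives separate animals for the replicates, so p-values measure the spread between these samples, which may in part be technical.

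Spot brightness was deposited as intensity from Agilent Feature Extraction 10.7.3.1, per the file headers, with a background surface subtracted and a multiplicative trend removed within each array but no normalization between arrays. Low values in these processed intensities are replaced by a surrogate from the scanner software's error model, which compresses differences among dim probes. Raw mean and local background intensities and flags of 0 or 1 per spot were deposited beside them. The deposited value table of the series holds log2 values, and limma is named without steps in the submitters' processing notes. Each of its columns correlated best with its own array. Its column medians were 6.42, 6.42, 6.42, 6.42, 6.42 and 6.41, and its lowest value was 5.65, close to the log2 of 50 (5.64). Values computed here with normexp at an offset of 50 and quantile normalization differed from it by a median of 0.02 to 0.03. Its exact steps stay unknown, and it was used as an alternative. All 6 arrays were on 1 slide in 1 scan. The untreated arrays were in one slide row and the aCXCR2 arrays in the other, so row and group cannot be told apart. The slide column equals the replicate number.

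Control spots and spots flagged as outliers were left out, and 0 spots were saturated on each array. The log2 processed signal was averaged over the spots of a probe and scaled by subtracting each array's 75th percentile. Of 55681 probes, those well above background on at least 3 of 6 arrays were kept, and for each gene the detected probe with the highest mean over the 6 arrays. Of the probes, 28325 were named by matching an accession to the reference gene table (assembly GRCm38.p6, used for names only), 2214 had a file symbol found in that table, and 25142 kept the file's name. Coordinates are those of the probe in the files, on build mm9. Of the genes named in the text, 16 had over 1 detected probe, and in 4 of them the probes differed in sign. The median coefficient of variation of repeated spots was 5.21% to 7.32% per array.

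Untreated 1 and 2 differed by about as much as repeated spots of 1 probe, and were averaged before the fit as 1 sample. The design fixed before the data were examined had 6 separate arrays. That fit is kept as an alternative. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), with Benjamini-Hochberg adjustment over 22755 genes at 0.05. Confidence intervals are at 95% from the moderated fit. The 37 gene lists, fixed before the data were examined, were tested two-sided with camera at a preset correlation of 0.01, adjusted over the lists. None of the calls held with an estimated correlation or with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. The lists hold macrophage states and pathways, dissociation stress and ribosomal protein genes, and markers of macrophages, monocytes, neutrophils, dendritic, T, NK, B and plasma cells, mast cells and eosinophils, luminal and basal epithelium, fibroblasts, smooth muscle, endothelium and red cells. Some genes stand in over 1 list. The median, mean and test of 3 lists (classical inflammatory, NF-kB and TNF, immune suppression) differ in sign.

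The rule for named genes was fixed before the data were examined. It took the sort markers, Cxcr2, 5 of its ligands and 12 activation genes whatever their result, then genes past the threshold without overlap between the groups' arrays (up to 8 per direction). As none passed, it took the 5 with the smallest p per direction among genes with a symbol and no overlap, and for each list past its threshold, and for the classical, alternative and NF-kB lists, the 3 members with the smallest p. S100a8, S100a9, Krt18, Svs5, Pbsn and Tgm4 were added after their values were seen.

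The fit was tested on 10 simulated data sets with the means and spreads of the 22755 genes, 200 genes changed by 2 or 4 on the log2 scale and 1 list shifted by 0.75. It recovered 13.1% and 52.7% of the genes changed by 2 and by 4, with 1.6 false calls per data set, and called the shifted list in 10 of 10. The simulated genes were independent of each other, unlike real ones. Alternatives covered the background correction, scaling, the filter on dim probes, the probe rule, the variance model, array weights, the replicate number as a block, the value table, and each array left out in turn. The slide position block is the same fit as the replicate block, because position and replicate number coincide. The averaging of untreated 1 and 2 and the restriction to RefSeq mRNA probes were chosen after the data were seen. So was the replicate block as fitted on 6 separate arrays. Figures were drawn with matplotlib 3.10.9.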

Results

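Gene expression was measured in macrophages sorted from whole prostates of C57BL/6 mice lacking Pten and Trp53, a mouse model of aggressive prostate cancer. The sort took cells positive for CD45 (encoded by Ptprc, a surface protein of leukocytes), CD11b (Itgam, an integrin of myeloid cells) and F480 (Adgre1, a macrophage marker). The mice either were labelled untreated or received aCXCR2, the compound AZD5069, at 100 mg/kg daily for 3 weeks by intraperitoneal injection. AZD5069 is an antagonist of CXCR2, the chemokine receptor best known for drawing neutrophils into tissue. The treatment protocol mentions a vehicle, so the untreated mice may have been given it. The series title names the question, which is how blocking CXCR2 changes tumour-associated macrophages. Each group had 3 single-colour arrays, all on 1 slide, with the untreated arrays in one slide row and the aCXCR2 arrays in the other. The 75th percentile of the processed signal was 248, 275 and 150 on the untreated arrays and 329, 153 and 282 on the aCXCR2 arrays. The share of probes well above background was 60.0%, 59.6% and 52.9% on the untreated arrays and 53.7%, 47.4% and 52.9% on the aCXCR2 arrays. All the mice shared 1 genotype. In log2 units over the array's 75th percentile, Pten signal was 2.29, 2.24 and 2.16 on the untreated arrays and 1.84, 2.29 and 2.67 on the aCXCR2 arrays, and Trp53 signal -2.14, -2.13 and -1.67 against -2.30, -2.31 and -1.75. Where these probes lie relative to the deleted parts is not given in the sources used here, so they check nothing about the genotype.

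The untreated arrays were not alike. Untreated 1 and 2 agreed within technical noise: over 13710 bright probes the spread of their log2 differences was 0.13, where repeated spots of 1 probe give about 0.12. They were therefore averaged and counted as 1 sample, which left 2 untreated samples against 3 aCXCR2 samples. Every other pair of arrays had a spread of 0.29 to 0.83. Untreated 3 stood apart from all of the others, with spreads of 0.76 to 0.83, whereas the aCXCR2 arrays differed among themselves by 0.42 to 0.52. The aCXCR2 3 array was closer to untreated 1 and 2 (0.33 and 0.29) than to aCXCR2 1 and 2 (0.42 and 0.52). In untreated 3, markers of other leukocytes and of fibroblasts were lower than in untreated 1 and 2, with medians of -2.86 for the monocyte list, -4.31 for the neutrophil list, -3.34 for the T cell list and -3.60 for the fibroblast list on the log2 scale. Mature macrophage markers were lower too, with a median of -0.95 (quartiles of -1.43 to -0.60). The basal epithelial markers of untreated 3 were higher, with a median of 2.50, while the smooth muscle and endothelial medians were 0.19 and 0.48. Because this 1 array makes up 1 of the 2 untreated samples, values without it are given for the lists, and for part of the named genes.

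**Figure D1:**
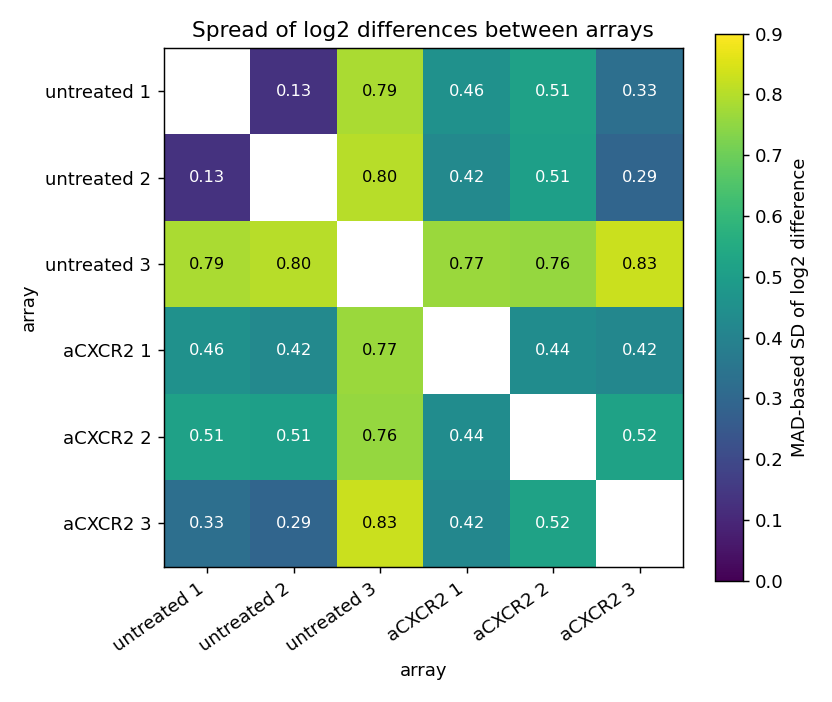
Spread (standard deviation estimated from the median absolute deviation) of log2 differences between each pair of arrays over 13710 bright probes, with arrays on both axes and the value in each cell. Untreated 1 and 2 are closest at 0.13, and all pairs with untreated 3 lie at 0.76 or above.

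No gene differed between the aCXCR2 and untreated samples at an adjusted p of 0.05. Of 22755 genes tested with limma, 1481 had an unadjusted p under 0.05, 651 of them higher and 830 lower with aCXCR2, where 1138 would be expected by chance. The balance of directions depends on the processing, with 902 higher and 710 lower with normexp background correction and 1381 higher and 506 lower with median scaling. Over the 5 samples the groups did not overlap in 23.01% of the genes, where chance gives 20% for 2 samples against 3, so lack of overlap in a single gene carries little weight. The smallest adjusted p was 0.285. On simulated samples with the spread of these genes, the same fit recovered 13.1% of genes changed by 2 on the log2 scale and 52.7% of genes changed by 4. Without untreated 3 no gene passed either, with 1320 at an unadjusted p under 0.05, 413 higher and 907 lower. That number was 893 without aCXCR2 1 and 774 without aCXCR2 2, and without aCXCR2 3 there were 732 higher and 641 lower.

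The sort markers differed by less than the test could call. Itgam was lower on every aCXCR2 array than on any untreated array, at 5.27 ± 0.23 (SD, n = 3) against 6.49 ± 0.75 (SD, n = 2) in log2 units over the array's 75th percentile, a difference of -1.21 with an adjusted p of 0.738 by limma. The other 2 detected Itgam probes, both dimmer, differed by -0.08 and -0.32. Ptprc differed by -0.84 ± 0.58 (SE) and Adgre1 by 0.76 ± 0.63, and by -1.19 and 0.30 without untreated 3, where the Itgam difference was -1.74. Cxcr2 itself, read by a probe at chromosome 1, 74206886 to 74206945 (mm9), was well above background on all 6 arrays. Its log2 signal was 0.56 and 0.58 in untreated 1 and 2 and -3.48 in untreated 3, and -1.82, -2.72 and -1.002 in aCXCR2 1, 2 and 3. The group difference was -0.39 ± 1.18 with untreated 3 and -2.42 without it, with an adjusted p of 0.947 in the first case. Without aCXCR2 2 the Cxcr2 difference was 0.04. The neutrophil list had a median of -0.28 with untreated 3, when it did not pass (adjusted p = 0.289 by camera), and -1.71 without it (adjusted p = 9.53e-12, or 0.815 with an estimated correlation). It turned to 0.21 without aCXCR2 2 (adjusted p = 0.499) and was -0.17 without aCXCR2 1 and -0.61 without aCXCR2 3. Its abundant members S100a8 and S100a9 were at 7.10 and 8.85 in untreated 1, at 1.34 and 1.37 in untreated 3, and between 3.20 and 5.39 and between 4.91 and 7.32, respectively, with aCXCR2.

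The CXCR2 ligands showed no difference beyond the replicate spread. Cxcl1 differed by -0.49 ± 0.29 (SE), Cxcl2 by -0.92 ± 0.42, Cxcl3 by -1.12 ± 0.52, Cxcl5 by 0.30 ± 0.38 and Ppbp by -1.31 ± 1.03, with adjusted p values of 0.738 to 0.851 by limma. Without untreated 3 these differences were -0.24, -1.21, -0.33, -0.02 and 0.58, so the last 2 changed sign. The list of CXCR2, its ligands and related cytokines and receptors also holds the signalling genes Grk2, Grk6, Arrb2 and Gnai2. This list had 10 of 15 members lower, a median of -0.18 and an adjusted p of 0.186 by camera. Its median was -0.24 without untreated 3. It was -0.10 without aCXCR2 2 (adjusted p = 0.174 by camera) and -0.52 without aCXCR2 3 (adjusted p = 0.0555). The list passed as lower in 2 of 21 alternatives, neither of which left out an array.

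No gene that marks inflammatory or alternative macrophage states passed the threshold on its own. Among the inflammatory genes, Tnf differed by -0.09 (95% confidence interval -0.86 to 0.69), Il1b by -1.04 (-2.17 to 0.10), Il6 by 0.53 (-0.74 to 1.80), Il12b by -0.33 (-2.24 to 1.58) and Nos2, the inducible nitric oxide synthase, by 1.61 (-0.26 to 3.48). Among genes of the alternative or suppressive state, Arg1 (arginase) differed by -0.39 (-1.11 to 0.33), Mrc1 (the mannose receptor) by 1.34 (-0.67 to 3.36), Il10 by 0.44 (-1.12 to 1.99), Tgfb1 by 0.55 (-0.61 to 1.72), Vegfa by -0.28 (-1.18 to 0.63) and Cd274, which encodes PD-L1, by -0.40 (-1.46 to 0.65). The 1 probe of Cd163 was above background on 0 arrays. The Nos2 and Mrc1 differences came from untreated 3, where they were at 0.80 and 0.73. Without it they were 0.23 and 0.24, and the differences were -0.52 for Tnf, -1.57 for Il1b, 0.33 for Il6, -1.10 for Il12b, -0.53 for Arg1, -0.36 for Il10, -0.07 for Tgfb1, -0.45 for Vegfa and -0.79 for Cd274, so Il10 and Tgfb1 changed sign. Without aCXCR2 2 the Il12b and Vegfa differences changed sign, to 0.25 and 0.02. The classical inflammatory list did not pass, with 12 of 25 members higher and 13 lower, a median of -0.09, a mean of 0.05 and an adjusted p of 0.716 by camera. Its 3 members with the smallest p were Il1a (-0.77 ± 0.28 SE), Ptgs2 (-1.16 ± 0.51) and Socs3 (-0.75 ± 0.33), each lower on all 3 aCXCR2 arrays than on any untreated array. The NF-kB and TNF response list did not pass either, with 15 of 27 members higher, a median of 0.14, a mean of 0.01, a test direction of lower and an adjusted p of 0.891. Nfkbiz differed by -1.01 ± 0.29 in it, Ccl4 by -1.06 ± 0.47 and Nfkbia by -0.52 ± 0.23. Without untreated 3 both lists passed as lower, the classical list with a median of -0.47 (adjusted p = 0.00129) and the NF-kB list with -0.22 (adjusted p = 0.00923). With an estimated correlation neither passed there (adjusted p = 0.815 for both). The classical median turned to 0.16 without aCXCR2 1 and 0.25 without aCXCR2 2, and the NF-kB median to -0.05 without aCXCR2 3.

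**Figure D2:**
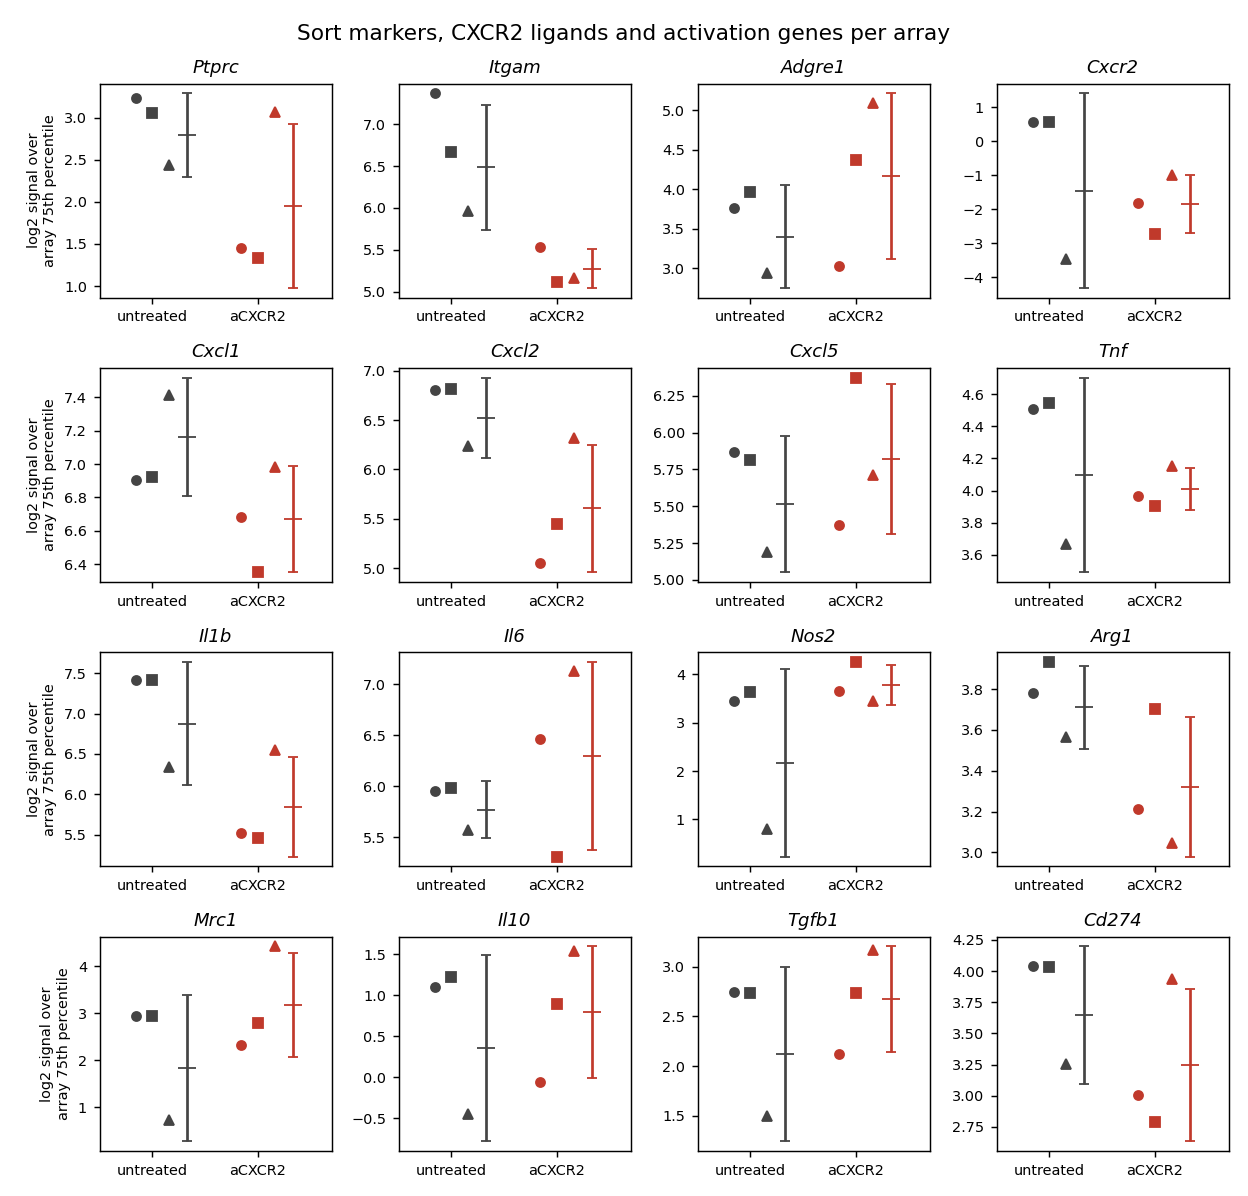
Log2 signal over the array's 75th percentile for sort markers, CXCR2, its ligands and activation genes (circle, square and triangle for replicates 1, 2 and 3, with mean and SD beside them over 2 untreated and 3 aCXCR2 samples, untreated 1 and 2 averaged first). Itgam does not overlap between the groups, and Nos2, Mrc1 and Cxcr2 are lowest in untreated 3.

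Proliferation genes and smooth muscle markers were the 2 lists that fell with aCXCR2 by camera. In the cell cycle list 24 of 31 members were lower, with a median of -0.58 (adjusted p = 7.34e-05). Plk1, a kinase of mitosis, was at 0.94 ± 0.09 (SD, n = 2) in untreated and -0.59 ± 0.06 (SD, n = 3) in aCXCR2 samples. Cdk1, which drives entry into mitosis, differed by -1.78 ± 0.49 (SE) and Cdc20, an activator of the anaphase-promoting complex, by -1.41 ± 0.44. In all 3 genes the aCXCR2 arrays lay below all untreated arrays. In the smooth muscle list 8 of 10 members were lower, with a median of -0.99 (adjusted p = 8.42e-05). Its contractile genes Actg2, Cnn1 and Tagln differed by -2.86 ± 0.42, -3.17 ± 0.49 and -1.06 ± 0.23. In smooth muscle both untreated samples lay above all aCXCR2 samples, with median deviations from the member means of 0.40 and 0.66 against -0.61, -0.33 and -0.04. In the cell cycle list untreated 3 did not stand above the aCXCR2 samples, at -0.21 against 0.96 for untreated 1 and 2 and -0.36, -0.50 and 0.01 for aCXCR2 1, 2 and 3, so the fall rests on untreated 1 and 2. Without untreated 3 the cell cycle median was therefore larger, at -1.19, and the smooth muscle median was -0.80. With an estimated correlation neither list passed (adjusted p = 0.894 for both). The median of the monocyte list was -1.28 without untreated 3, and T cell and fibroblast markers fell by as much there (-1.21 and -1.26). In that contrast the lower proliferation genes went with lower markers of several cell types. With untreated 3 they did not, as the monocyte, T cell and fibroblast medians were positive (0.50, 0.45 and 0.81).

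Prostate luminal and endothelial markers rose with aCXCR2 by camera, although the sort should exclude these cells. In the luminal list 26 of 29 members were higher, with a median of 0.81 (adjusted p = 7.23e-07). The list also holds seminal vesicle secretion genes such as Svs5, at 3.32 in untreated 3 and 10.01 or above on the other arrays. Its prostate secretory members Pbsn and Tgm4 went the other way, with their highest signal in untreated 3 (2.77 and 2.20). Sbp (spermine-binding protein) differed by 3.41 ± 0.94 (SE), Spink1 (a secreted trypsin inhibitor) by 2.52 ± 0.75 and Cldn4 (a tight junction protein) by 1.43 ± 0.51, against 3.47, 1.65 and 0.68 without untreated 3. In the endothelial list 15 of 17 members were higher, with a median of 0.74 (adjusted p = 0.000102). Cldn5 differed by 1.62 ± 0.46, Ptprb by 1.76 ± 0.52 and Flt1 by 0.89 ± 0.32. In each list 1 aCXCR2 sample was about level with an untreated sample. The luminal deviations were -0.45 and -0.55 in the untreated samples and 0.74, 0.64 and -0.40 in aCXCR2 1, 2 and 3, and the endothelial ones -0.67 and -0.23 against -0.28, 0.27 and 0.85. Without untreated 3 the medians were 0.68 and 0.98 and both lists still passed. Without aCXCR2 3 the endothelial median was 0.40, and the list still passed (adjusted p = 0.0177). With an estimated correlation neither passed (adjusted p = 0.894 for both). The epithelial keratin gene Krt18 was well above background on all 6 arrays, from 9.01 to 10.004 in log2 units over the 75th percentile. It differed by 0.25 ± 0.39 between the groups. On the same scale the sort markers Ptprc, Adgre1 and Itgam were at 1.33 to 3.24, 2.94 to 5.09 and 5.12 to 7.37. Levels of different probes do not measure cell shares, but differences between the groups cannot be assigned to macrophages alone.

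Lists of immune activity that rose with aCXCR2 lost their calls without untreated 3. The interferon response list had 37 of 40 members higher and a median of 0.87 (adjusted p = 2.28e-07 by camera), and a median of -0.00335 without untreated 3 (adjusted p = 0.969), with 20 of 40 higher. Its members Ifit3, an interferon-induced antiviral gene, and Irgm1, an immunity-related GTPase, differed by 1.77 ± 0.63 (SE) and 1.75 ± 0.62 with that array and by 0.64 and 0.64 without it. The member with the smallest p, Gbp6, went the other way, at -3.72 ± 0.47 (-3.22 without untreated 3), while its other probe differed by 1.30. The complement list had 16 of 18 members higher and a median of 0.91 (adjusted p = 0.00129), against 0.31 without untreated 3 (adjusted p = 0.654). C3 differed by 1.68 ± 0.72 and Serping1, the C1 inhibitor, by 1.55 ± 0.66 (0.49 and 0.52 without untreated 3), while Itgam, the third complement list member named, was lower. The alternative macrophage list had 21 of 25 members higher and a median of 0.64 (adjusted p = 0.00164), against 0.18 without untreated 3 (adjusted p = 0.969). Ccl24, an eosinophil-attracting chemokine, differed by 2.46 ± 0.89, and the lectin genes Cd209f and Clec10a by 1.97 ± 0.73 and 1.78 ± 0.72. Without untreated 3 these were 1.65, 1.698 and 0.82. The MHC class I list had 17 of 18 members higher and a median of 0.42 (adjusted p = 0.00214), against -0.07 without untreated 3 (adjusted p = 0.479), with B2m, Psmb10 and Tap1 at 0.62, 1.20 and 0.96 in the first case and 0.01, 0.25 and -0.06 in the second. Without aCXCR2 1 the alternative median was 1.03 (adjusted p = 4.98e-07). Without aCXCR2 3 the alternative list (0.30, adjusted p = 0.150) and the complement list (0.55, adjusted p = 0.0810) did not pass either. With an estimated correlation none of these 4 lists passed (adjusted p = 0.894 for each).

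Mast cell and eosinophil markers, fibroblast markers and 3 metabolic lists also rose by camera. The mast cell and eosinophil list had a median of 0.84 (11 of 13 higher, adjusted p = 0.00112), with the mast cell protease gene Tpsb2 at 1.46 ± 0.33 (SE), Fcer1a at 2.04 ± 0.89 and Cma1 at 1.57 ± 0.71 (1.31, 0.63 and 0.54 without untreated 3). Its median without untreated 3 was 0.42 (adjusted p = 0.328). The fibroblast list turned direction, unlike its 3 members named here. Its median was 0.81 (17 of 21 higher, adjusted p = 0.0166), with Sfrp1, Pi16 and Mfap5 at 1.65 ± 0.59, 1.69 ± 0.64 and 1.12 ± 0.47, and -1.26 without untreated 3 (adjusted p = 0.000999, or 0.815 with an estimated correlation), where these 3 genes were at 0.97, 0.88 and 0.73. The oxidative phosphorylation list had a median of 0.17 (27 of 30 higher, adjusted p = 0.00685) and 0.20 without untreated 3 (adjusted p = 0.0160), with the respiratory chain and ATP synthase genes Ndufs2, Ndufs8 and Atp5a1 at 0.61 ± 0.35, 0.50 ± 0.29 and 0.41 ± 0.25 with untreated 3 and at 0.17, 0.40 and 0.20 without it. The cholesterol synthesis list had a median of 0.25 (19 of 24 higher, adjusted p = 0.0148) and 0.19 without untreated 3 (adjusted p = 0.133), with Sc5d, Pmvk and Fdft1 at 0.87 ± 0.29, 0.58 ± 0.27 and 0.91 ± 0.45 with untreated 3 and at 0.87, 0.49 and 0.39 without it. The glycolysis list had a median of 0.26 (16 of 20 higher, adjusted p = 0.0204) and -0.02 without untreated 3 (adjusted p = 0.780), with Gpi1, Pfkfb3 and Aldoc at 1.00 ± 0.43, 0.59 ± 0.27 and 1.31 ± 0.62 with untreated 3 and at 0.30, 0.30 and 0.47 without it. The other 2 detected Gpi1 probes, nearly as bright, differed by 0.22 and 0.37. The other detected Fdft1 probe, which was dimmer, differed by -0.32. Over 21 alternatives of processing, array left out or list test, the fibroblast list passed in 13, 1 of them in the other direction, and glycolysis in 12. The cholesterol list passed in 15, the oxidative phosphorylation list in 16 and the mast cell and eosinophil list in 18. Leaving out an aCXCR2 sample also ended calls. The fibroblast list did not pass without aCXCR2 1 (0.55, adjusted p = 0.0887) or 3 (0.46, 0.368), the cholesterol list without 1 (0.27, 0.0532) or 2 (0.15, 0.173), the glycolysis list without 2 (0.17, 0.0863) or 3 (0.29, 0.0555), and the oxidative phosphorylation list without 2 (0.06, 0.232). Medians of lists that passed moved up too, to 1.29 for fibroblast without aCXCR2 2 and to 0.56 for cholesterol and 0.29 for oxidative phosphorylation without aCXCR2 3, whose deviations in the last 2 lists (-0.22 and -0.17) were about those of the untreated samples (-0.02 and -0.13 in untreated 1 and 2, -0.26 and -0.10 in untreated 3). With an estimated correlation none of these 5 lists passed (adjusted p = 0.894 for each).

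**Figure D3:**
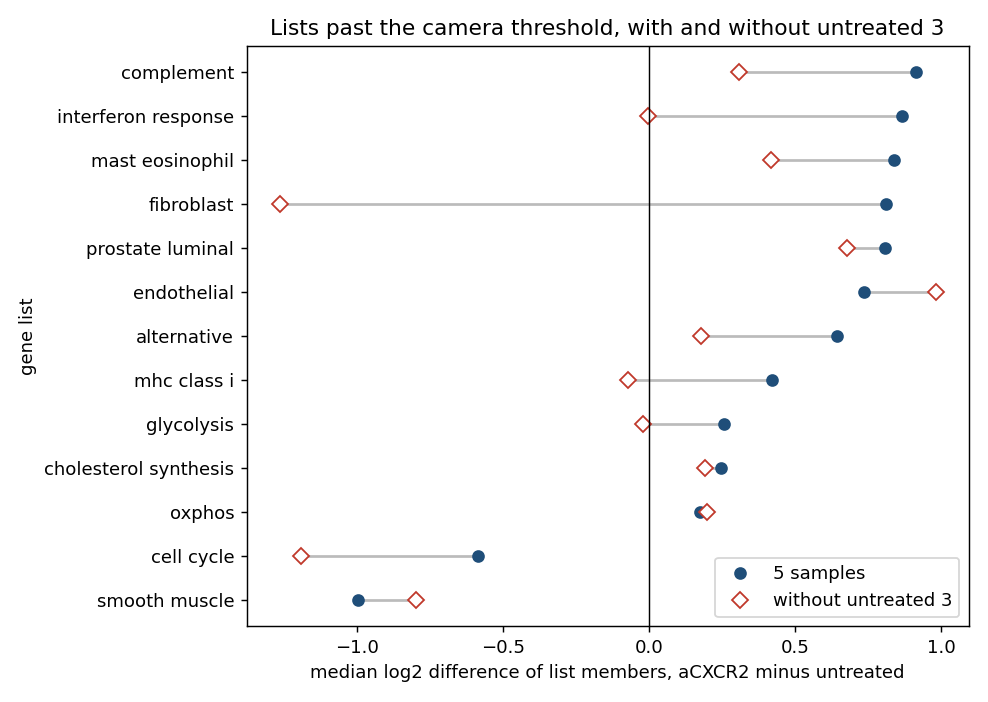
Median log2 difference, aCXCR2 minus untreated, of the members of each of the 13 gene lists past the camera threshold, in all 5 samples (filled circles) and without untreated 3 (open diamonds). The interferon response (-0.00335), glycolysis (-0.02) and MHC class I (-0.07) lists move just past 0, and the fibroblast list moves from 0.81 to -1.26. The other lists keep their side of 0.

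The other 24 of the 37 lists did not pass. Their medians were 0.44 for mature macrophage markers (13 of 16 higher, adjusted p = 0.154 by camera) and 0.69 for MHC class II (adjusted p = 0.0523). The chemokine list, of CC chemokines, Cxcl12, Cxcl13, Cxcl14, Cxcl16 and chemokine receptors, had a median of 0.59 (0.0523). Medians were 0.23 for lysosome genes (0.130), 0.19 for phagocytosis receptors (0.258), 0.16 for lipid handling (0.300) and 0.37 for matrix and angiogenesis genes (0.512). They were 0.28 for hypoxia genes (0.810), 0.09 for iron and haem genes (0.891) and 0.13 for immune suppression genes (0.920). The list of p53 targets and cell-cycle inhibitors had a median of 0.12 (14 of 22 higher, adjusted p = 0.891). Dissociation stress genes had a median of 0.17 (adjusted p = 0.535) and ribosomal protein genes 0.05 (0.535). Among other cells, the medians were 0.50 for monocyte (0.258), 0.39 for dendritic cell (0.342), 0.45 for T cell (0.289), 0.76 for NK cell (0.291), 0.87 for B and plasma cell (0.147), 0.91 for red cell and platelet (0.646) and -0.30 for basal epithelial markers (0.289). Without untreated 3 several of these passed at the preset correlation: basal epithelial (0.83, adjusted p = 1.53e-06), T cell (-1.21, 0.000274), immune suppression (-0.64, 0.000206), matrix and angiogenesis (-0.42, 0.00088), hypoxia (-0.28, 0.00128), lysosome (-0.28, 0.00654) and ribosomal protein genes (0.16, 0.0341). With an estimated correlation 0 lists passed there, with adjusted p values of 0.815 for the first 5 of these, 0.856 for lysosome and 0.870 for ribosomal protein genes. The other medians without untreated 3 were 0.12 for mature macrophage, 0.05 for MHC class II, 0.05 for chemokine and -0.23 for phagocytosis receptor genes. They were -0.14 for lipid handling, 0.03 for iron and haem, 0.05 for p53 and 0.06 for dissociation stress genes. For other cells they were -0.36 for dendritic cell, -0.45 for NK cell, -0.68 for B and plasma cell and -0.69 for red cell and platelet genes. Some of the 24 lists passed under alternatives of processing as well. Over all 21 alternatives, arrays left out included, the chemokine list passed in 6, MHC class II in 5 and ribosomal protein genes in 4. The neutrophil and the B and plasma cell lists passed in 3 each. At the preset correlation, leaving out another array also gave calls. Without aCXCR2 1 these were mature macrophage (0.92, adjusted p = 7.15e-05 by camera), MHC class II (1.08, 0.00038), chemokine (0.95, 0.00197), lysosome (0.42, 0.00265), phagocytosis receptors (0.45, 0.00624) and lipid handling (0.32, 0.00854). Without aCXCR2 2 they were chemokine (0.73, 0.00302), T cell (0.99, 0.00492) and B and plasma cell (1.42, 0.00948), and without untreated 1 MHC class II (0.70, 0.0454). Without aCXCR2 3 the medians were smaller, at 0.17 for mature macrophage, 0.34 for MHC class II and 0.30 for chemokine genes. They were 0.07 for lysosome, 0.01 for T cell and 0.39 for B and plasma cell genes. These lists had adjusted p values of 0.598 to 0.998 by camera there. The medians of phagocytosis receptors (-0.06), lipid handling (-0.00745) and immune suppression (-0.16) changed sign. No member of any of the 37 lists passed an adjusted p of 0.05 over all genes. Adjusted over the list alone, 4 smooth muscle members, 1 interferon response member and 1 B and plasma cell member passed.

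Of genes with a symbol and no overlap between the groups' arrays, those with the smallest p are named here, all of them short of the threshold. The 5 of them that were lower with aCXCR2 were Syn3, Prr3, Cd300lf, Gbp6 and Mrgprg, picked by p and not by size. Their differences were -4.23 ± 0.45 (SE), -2.64 ± 0.33, -3.38 ± 0.43, -3.72 ± 0.47 and -3.44 ± 0.46, with adjusted p values of 0.285 to 0.289 by limma. Syn3 encodes a synapsin, Mrgprg an orphan G protein-coupled receptor, Cd300lf an inhibitory receptor of myeloid cells and Gbp6 an interferon-induced GTPase. The Syn3 probe is not annotated to a RefSeq mRNA, so it does not show that synapsin mRNA fell. Other detected probes of Cd300lf and Gbp6 did not move with them, and Syn3, Prr3 and Mrgprg had 1 detected probe each. The other 2 detected Cd300lf probes differed by 0.44 and 0.49, and the other Gbp6 probe by 1.30. The Gbp6 probe named here lies at chromosome 5, 105644259 to 105644318, and the Cd300lf probe at chromosome 11, 114977796 to 114977855 (both mm9). The 5 picked in the same way that were higher with aCXCR2 had adjusted p values of 0.375 to 0.447 by limma. They were Dzip1 (2.30 ± 0.38), Clcnkb, a chloride channel gene (2.52 ± 0.43), Lpo, which encodes lactoperoxidase (3.09 ± 0.53), Bhlha15, a transcription factor of secretory cells (3.02 ± 0.58) and Ctxn2 (3.85 ± 0.75). The Dzip1 probe named here is annotated to a noncoding transcript. A second, dimmer Dzip1 probe, annotated to a RefSeq mRNA, differed by -0.09. Ctxn2 was above background on 1 of 3 untreated arrays. Without untreated 3 the differences of these 10 genes ran from -3.81 to 2.97 and kept their sign. Among the genes named further above, Fcer1a and Ccl24 were above background on 2 of 3 untreated arrays. Cdk1 and Il12b were so on 2 of 3 aCXCR2 arrays.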

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

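The fit on 6 separate arrays without a block was the design fixed before the data were examined. The 5-sample fit, the replicate block on 6 separate arrays and the fit on RefSeq mRNA probes alone were chosen after the data were seen. By limma, 0 genes passed an adjusted p of 0.05 in the 5-sample fit and under each alternative, and the 5-sample fit gave 1481 at an unadjusted p of 0.05. At an adjusted p of 0.1 that fit gave 0 genes. The smallest adjusted p ran from 0.0716 with normexp to 0.973 without aCXCR2 replicate 1, and lay under 0.1 with normexp and with 6 separate arrays (0.0821). Leaving out 1 array at a time gave 0 genes each time and 774 to 1715 at an unadjusted p under 0.05. RefSeq mRNA probes alone gave 800 of those, 514 higher and 286 lower. The median of all genes moved from 0.0028 to 0.18 with median scaling, where 1381 genes at that p were higher and 506 lower, against 651 and 830 with the 75th percentile, and normexp gave 902 and 710, so directions of small changes depend on the processing. Of gene lists, 13 passed with camera, and 10 to 16 under the alternatives of processing, but 0 with an estimated correlation (smallest adjusted p 0.894) and 0 with fry (0.780). The first allows for members that vary together, as members of a list did across these samples. Leaving out 1 array at a time gave 9 to 17 lists.

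Without untreated replicate 3 the untreated group is 1 sample, assumed to vary like the aCXCR2 samples, and 5 of the 13 lists kept their call and direction. The test direction of 20 of the 37 lists turned, and 10 of these were past the threshold with or without that array. Over the arrays left out in turn the medians of the 10 ran from 0.18 (without untreated 3, test direction lower) to 1.03 for alternative genes and from -0.52 to 0.83 (without untreated 3) for basal epithelial genes. In the others the lowest value came without untreated 3: -0.42 to 0.41 for matrix and angiogenesis, -1.26 to 1.29 for fibroblast, -0.0211 to 0.29 for glycolysis, -0.28 to 0.37 for hypoxia, -0.28 to 0.42 for lysosome, -0.0718 to 0.51 for MHC class I, -1.28 to 0.53 for monocyte and -1.21 to 0.99 for T cell genes. The cause was not tested beyond the values of that array. Cell cycle, smooth muscle, endothelial and luminal lists passed in 19 of 21 alternatives each, the exceptions being the estimated correlation and fry. Of 1381 values of named genes under the alternatives, 0 passed the threshold and 10 changed sign.

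With the replicate block, fitted on 6 separate arrays, 0 genes and 11 lists passed. The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated across genes at 0.12, -0.27 and -0.26, and not every array correlated best with its own number. Without the block, 6 separate arrays gave 0 genes, a smallest adjusted p of 0.0821 and 11 lists. Signal over background limits the rest, since 47.4% to 60.0% of the probes on an array were well above background.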

Other observations

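Apart from the count of receptor probes over all untreated arrays, the order of macrophage markers and the splits of the samples, the tests below were chosen after the result was seen, and the genes named in this part were chosen after their values were seen. Untreated 3 had a profile of its own. The prostate secretory genes Pbsn and Tgm4 were at 2.77 and 2.20 in log2 units over the 75th percentile there and at or below -1.65 and -2.98 on the other arrays. Cyp1a1 and Nqo1, which encode enzymes of xenobiotic metabolism, were at 2.93 and 3.01 against at most -1.97 and -1.82 elsewhere. The basal epithelial genes Krt5 and Col17a1 were at 7.89 and 4.28 against at most 4.75 and 1.15. The seminal vesicle secretion genes Svs2, Svs4 and Svs5 were at 0.49, 0.97 and 3.32 in untreated 3 and at 7.62 or above on the other 5 arrays, although the sort should exclude the cells that make them. These are values of 1 array, with no test.

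That untreated 3 stands apart is not explained by low signal on its array: among 7585 genes with the highest signal, 821 lay over 2-fold outside all other samples, against 26 for aCXCR2 2, the array of nearly the same 75th percentile. A lower share of leukocytes with all other cells raised alike is argued against too, since basal epithelial markers were higher and fibroblast markers lower than in untreated 1 and 2, 6.09 apart in median, with quartiles of 1.45 to 3.93 and -4.49 to -2.03. Swapped labels of untreated 3 and aCXCR2 3 would place untreated 3 near aCXCR2 1 and 2, but its mean spread to them was 0.76. Untreated 3 lay 0.76 to 0.83 from every other array, so this spread cannot decide on a swap. The aCXCR2 3 array lay closer to untreated 1 and 2 (0.33 and 0.29) than to aCXCR2 1 and 2 (0.42 and 0.52). Such a swap therefore stays open. A sample with more basal epithelial RNA and less fibroblast and leukocyte RNA, macrophage RNA included, stays open. Mature macrophage, endothelial and smooth muscle markers of untreated 3 were at -0.95, 0.48 and 0.19 against untreated 1 and 2. A single wrong label or a swap with an outside sample, and a difference between mice, stay open too. No biological explanation was tested, since no label sets this mouse apart.

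Probes for noncoding transcripts were detected more often on the untreated arrays. Over 16249 lincRNA probes the share well above background was 42.6%, 41.9% and 35.7% on the untreated arrays and 32.8%, 25.02% and 32.2% on the aCXCR2 arrays, and 662 probes of any class were above background on all untreated and no aCXCR2 array, against 38 the other way. Array brightness alone did not order these shares, as the 75th percentile ranges overlapped, at 150 to 275 and 153 to 329. The lowest untreated share exceeded the highest aCXCR2 share by 2.94 percentage points, and by 9.12 without untreated 3. The counting error of 0.526 on the first gap covers the probes counted and not the spread between samples. With 2 samples against 3, groups do not overlap in 20% of cases by chance, so array brightness is not excluded. By median signal aCXCR2 2 was dimmer than untreated 3, at 15.5 against 16.2, and it had the lowest lincRNA share. For 1493 olfactory and vomeronasal receptor probes, for which little transcript is expected, the shares were 13.5%, 12.7% and 6.90% on the untreated and 8.57%, 7.10% and 7.90% on the aCXCR2 arrays, a gap of -1.67 (counting error 0.977). The bound set before the count was 0 or below, but the gap rests on untreated 3 alone. Without that array, a comparison chosen after the count, the gap was 4.15 (counting error 1.13). Untreated 1 and 2 both lay above every aCXCR2 array, but they count as 1 sample, so this sets 1 sample against 3. This counting error leaves out the spread between samples too. Weak unspecific signal is therefore not excluded, and for untreated 1 and 2 it stays a candidate explanation. Position on the slide and treatment cannot be told apart, because 0 slide rows hold both groups, and an effect of CXCR2 blockade on these transcripts stays open with it.

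Large single-probe differences went with this. Of 247 probes lower by over 2 on the log2 scale without overlap, 69 were RefSeq mRNA and 97 lincRNA probes, against 196 and 7 of 244 probes higher by as much. In 92 genes with such a lower probe and other detected probes, the median of the others was -0.41, and it was 1.31 in 44 genes with such a higher probe.

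Cxcr2 signal was lower in untreated 3 and in the aCXCR2 samples than in untreated 1 and 2. All 10 of 10 pairs of the 5 samples were ordered alike by Cxcr2 and by the median of the other neutrophil markers, but the T cell, NK cell, fibroblast, classical inflammatory and p53 lists gave 10 of 10 as well, so this order does not single out neutrophil RNA as the source, which stays open. The F480 gate should exclude neutrophils. By Cxcr2 and the mature macrophage markers 6 of 10 pairs were ordered alike, but 2 of the other 4 pairs of medians differed by less than their standard error (a margin chosen after the count), so up to 8 can be alike and macrophage RNA as the source stays open too. What the treatment does to Cxcr2 within a cell type was not tested and stays open.

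With 5 samples, 2 against 3, there are 10 splits, too few for a share under 0.05. The real split gave 1481 genes at an unadjusted p under 0.05 and the highest other split 2500, and 3 of 10 splits gave as many. It gave 13 gene lists, and the highest other split 30, with as many lists in 9 of 10 splits. The split with 30 lists, over 2 times the real number, set untreated 1 and 2 with aCXCR2 3 against the rest. It gave 1729 genes, while the split with 2500 genes set untreated 3 with aCXCR2 2 against the rest. Both splits were picked after the counts were seen, so they do not settle how the samples are structured.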
